A study of Rattus norvegicus with 12 samples.

How the data were processed

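The series compared kidneys of inbred male Lewis rats, in which a kidney moved between animals is an isograft, that is a graft between genetically alike animals. Per the design text, donors were either living or brain dead. Brain death was brought about by a gradual rise of intracranial pressure, and these donors were then ventilated for 6 h. The left kidney was transplanted orthotopically, with an operative ischemia of 30 min, and the recipient's own right kidney was removed. RNA of each kidney or graft was labelled with Cy3 and hybridised together with Cy5-labelled RNA of a mixture of 3 normal kidneys, a common reference, on 2-channel Agilent rat oligonucleotide arrays. There were 12 arrays in 4 groups of 3: normal kidneys, kidneys of brain dead donors before transplantation (0 h), grafts of living donors 1 h after transplantation and grafts of brain dead donors 1 h after transplantation. Whether the 3 kidneys of the reference mixture were also hybridised singly as the normal group is not given in the sources used here.

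Groups were taken from the sample titles. The free-text description is the same on all 12 arrays and speaks of a brain dead donor and of 1 h after transplantation, which the titles contradict for 9 of them, so it was not used. The design text speaks of individual grafts, with 1 array for each. Nothing in the labels says more about the animals behind the replicates, so p-values measure the spread between these samples.

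The deposited table holds 21575 probes with a value on every array. Per the design text, the authors scanned the arrays, extracted spots with Agilent Feature Extraction, normalized each array in GeneSpring 7.0 (by spot, by chip and with an intensity-dependent lowess curve) and used the Cy3 over Cy5 ratio. Which of these programs wrote the deposited values is not given in the sources used here. The deposited values were read as log10 ratios, for these reasons: they lie around 0, they end exactly at 2 on either side (a ratio of 100, the limit Agilent's software sets), and array medians are near 0. Linear ratios had been assumed when the design was fixed, and the test was therefore run on the log10 values multiplied by 3.322, which gives log2 ratios. The direction, sample over normal reference, rests on the design text. All exact zeros in the table carry a minus sign, which a change of sign from Cy5 over Cy3 would leave.

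No intensities were used here, so background, saturation and dim spots could not be weighed, and low transcripts cannot be told from spots near background. The number of arrays limits the precision. Exact zeros made up 0.70% of values (1817, of which 433 lie on named probes) and were kept as deposited. Control spots could not be told from unnamed probes. Neither slide nor scan date is given in the sources used here, so no batch could be tested. Array medians of the log2 ratio lay between 0 and 0.0099, and no further normalization between arrays was applied. Pairs of arrays correlated with r from 0.709 to 0.956 over named genes and unnamed probes together.

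Gene symbols came from the platform annotation table that was supplied with the values. Of the probes, 12750 had 1 symbol, 5 had several and 8820 had none. Of 12755 annotated Entrez identifiers, 12720 were present in the current RefSeq gene table of the rat (assembly GRCr8), which served only for names. Log2 ratios of probes with the same single symbol were averaged, which left 18478 features: 9653 named genes and 8825 unnamed probes. A gene with more than 1 probe (2266 genes) can hide probes that disagree. Large differences are stated for genes chosen by the size of their change. For other genes named in the text, single probes are not given. No genome build enters the values, so no coordinates are given.

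Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 12 arrays, with 8 residual degrees of freedom per feature and a prior of 1.89 degrees of freedom. A moderated test gave a p for each feature in 5 contrasts: brain dead donor kidneys against normal kidneys at 0 h, brain dead against living donor grafts at 1 h, living donor grafts at 1 h against normal kidneys, brain dead donor grafts at 1 h against brain dead donor kidneys at 0 h, and the interaction of donor and time. Fold changes are log2 differences with their standard error. P-values were adjusted with the Benjamini-Hochberg method over the 18478 features of a contrast, and a feature passed at an adjusted p under 0.05. All adjusted p-values of single genes in the text are from this limma fit.

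Groups, contrasts, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, for each group comparison, the 12 largest increases and 12 largest decreases among genes that passed, had a single symbol not starting with LOC or RGD, and showed no overlap of replicates. It names the 5 genes with the smallest p for the interaction where none passes, and up to 4 members with the smallest p of each list that is described. A gene that 2 parts of the rule name counts under both.

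There were 30 lists from textbook knowledge. Of them, 19 cover pathways: immediate early, heat shock, tubular injury, cytokine, NF-kB, STAT3 and acute phase, endothelial activation, hypoxia, oxidative stress, p53 and apoptosis, unfolded protein and ATF4, glucocorticoid, antigen presentation, interferon, fatty acid oxidation, vasoactive, extracellular matrix, complement and cell cycle genes. The other 11 cover cell types: proximal tubule, distal nephron, podocyte, endothelium, neutrophil, monocyte and macrophage, T and NK cell, B cell, red cell and platelet, smooth muscle with pericyte and fibroblast, and adipose genes. Of 768 listed genes, 598 were measured. Lists were tested with limma's camera at a preset correlation of 0.01, which asks whether a list moved more than the other genes, with Benjamini-Hochberg adjustment over the 30 lists of a contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction without comparing them with other genes, were alternatives.

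Scripts were tested on simulated data made from the real arrays' means and spreads, with known changes put into a set of the 18478 features. At a log2 change of 1, limma recovered 85.1% of changed features for brain dead against normal kidney at 0 h, 80.6% for brain dead against living donor grafts, 86.6% for living donor grafts against normal kidney and 80.6% for brain dead donor grafts against brain dead donor kidneys at 0 h. At a log2 change of 0.5 these shares were 38.8%, 56.7%, 58.2% and 53.7%. False calls made up 3.3%, 4.8%, 5.8% and 3.2% of calls. Each comparison had a single simulation, with 66 or 67 features changed at each size and noise drawn independently for each feature. Genes on the real arrays are correlated (estimated at up to 0.319 within a list), so these shares need not hold for the real data.

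Alternatives covered centring and quantile normalization between arrays, a pseudocount of 0.1 on the ratio, ratios limited to 0.1 to 10, probes as single features, robust eBayes, array weights, fits of only the 2 groups compared, a threshold of 2-fold, the replicate number as a block in a fit of the 0 h groups alone, and each array left out in turn. Exact zeros taken as missing and named genes alone were added after seeing the data.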

Results

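Rat kidneys were profiled on 12 arrays, 3 in each of 4 groups: normal kidneys, kidneys of brain dead donors before transplantation (0 h), and grafts of living and of brain dead donors 1 h after transplantation. Each array measured 21575 probes as the log2 ratio of the sample over pooled normal kidney RNA, and 9653 named genes and 8825 unnamed probes were tested. Over all 18478 features, each array's mean correlation was 0.851 to 0.94 with its own group and 0.78 to 0.878 over the arrays of all other groups, with replicate 21 of the brain dead donor grafts lowest in both. Replicates 23 and 27 of these grafts lay closer to the brain dead donor kidneys at 0 h (mean r of 0.909 and 0.907) than to their own group (0.886 and 0.884), and correlated with each other at 0.918. The median SD of named genes between replicates was 0.0865 log2 units in normal kidneys, 0.0878 in brain dead donor kidneys, 0.0919 in living donor grafts and 0.1046 in brain dead donor grafts.

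The comparison of brain dead donor kidneys with normal kidneys at 0 h asked what brain death with 6 h of ventilation had done to the kidney before it was transplanted. No array is labelled as a ventilated donor without brain death, so brain death and ventilation cannot be told apart here. Selp, the adhesion molecule P-selectin of activated endothelium and platelets, was 17.9-fold higher (log2 4.16 ± 0.58, SE, n = 3 arrays per group, adjusted p = 0.00608). Ccl2, a chemokine that attracts monocytes, was 17.6-fold higher (log2 4.14 ± 0.57, adjusted p = 0.00608). Rnd1, a small GTPase that acts on the actin cytoskeleton, was 17.4-fold higher (log2 4.12 ± 0.50, adjusted p = 0.00377). S100a9, a calcium-binding protein abundant in neutrophils, rose 11.1-fold (log2 3.47 ± 0.50). Birc3, an inhibitor of apoptosis, rose 10.1-fold (log2 3.34 ± 0.40), and Sele, the endothelial E-selectin, rose 9.91-fold (log2 3.31 ± 0.67). Il1b, the cytokine interleukin 1 beta, rose 8.26-fold (log2 3.05 ± 0.32), and the chemokines Cxcl10 and Cxcl1 rose 7.87-fold (log2 2.98 ± 0.70) and 6.78-fold (log2 2.76 ± 0.43). Map3k8, a kinase of inflammatory signalling, Vcam1, a vascular adhesion molecule, and Cebpd, a transcription factor of the acute phase response, rose by 2.35 ± 0.27, 2.32 ± 0.46 and 2.26 ± 0.33 on the log2 scale.

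Decreases in brain dead donor kidneys were smaller. Tmem204, a transmembrane protein of endothelium, fell by 1.87 ± 0.23 on the log2 scale, to 0.274 of the level in normal kidney (adjusted p = 0.00389). S100pbp fell to 0.353 of the normal level and Spag8 by 1.49 ± 0.25 on the log2 scale. Falls were also seen in Nr0b2, a nuclear receptor that represses transcription (-1.23 ± 0.28), and in the aldo-keto reductase Akr1c19 (-1.15 ± 0.16). Tet1, an enzyme that oxidises methylcytosine, Sostdc1, a secreted inhibitor of BMP and Wnt signals, and Ska2, a protein of the mitotic spindle, fell by 1.10 ± 0.20, 1.07 ± 0.16 and 1.05 ± 0.16. Inpp5j, Jag1, a Notch ligand, Mllt10 and Gja5, the gap junction protein connexin 40, fell by 1.04 ± 0.16, 1.01 ± 0.17, 1.00 ± 0.16 and 0.96 ± 0.20. The 2 probes of Mllt10 differed (log2 -1.75 and -0.24), as did the 2 of Spag8 (-1.92 and -1.06).

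In all, 860 of 18478 features passed in limma with Benjamini-Hochberg adjustment, 419 higher and 441 lower. Of these, 505 were named genes (265 higher, 240 lower). Of the 860, 123 changed at least 2-fold (98 higher, 25 lower). All 860 showed no overlap between the replicates of the groups, against 23.9% of all features and 10% by chance. The count was 2852 with array weights and 350 in a fit of the 2 groups alone. Adding the replicate number as a block to that fit left 2, and whether the numbers pair the arrays is not settled. The count was 165 or 333 without replicate 2 or 3 of the brain dead donor kidneys. Without replicate 1, 2 or 3 of the normal kidneys it was 304, 239 or 362. The lower share, 51.3%, was 34.5% without replicate 1 of the normal kidneys and 37.6% or 39.6% without replicate 2 or 3 of the brain dead donor kidneys. Of the 24 genes named above, 13 passed whichever array was left out. Those that did not were Sele, Cxcl10, Vcam1, S100pbp, Spag8, Nr0b2, Tet1, Ska2, Jag1, Mllt10 and Gja5 (highest adjusted p 0.161, for Cxcl10).

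Among gene lists at 0 h, 5 passed camera upwards both with the preset and with an estimated correlation. Of 21 measured NF-kB targets and feedback genes, 7 rose (15 adjusted over the list alone), with a median log2 fold change of 0.46. Among them were Birc3, Nfkbia, the inhibitor that holds NF-kB in the cytoplasm (log2 1.72 ± 0.21), the receptor Tlr2 (1.59 ± 0.27) and Bcl3 (1.47 ± 0.25). Of 21 endothelial activation and coagulation genes, 7 rose (8 adjusted over the list alone, median 0.21), among them Icam1 (1.75 ± 0.16) and Plat, tissue plasminogen activator (0.68 ± 0.09), beside Selp and Vcam1. Of 23 unfolded protein and ATF4 response genes, 6 rose (8 adjusted over the list alone, median 0.30), among them Sesn2 (1.15 ± 0.12), the transcription factor Atf4 (0.89 ± 0.10), Herpud1 (0.65 ± 0.08) and Ppp1r15a, a subunit of the phosphatase of eIF2 alpha (1.17 ± 0.18). Of 28 oxidative stress and metallothionein genes, 6 rose (8 adjusted over the list alone, median 0.08), among them the metallothioneins Mt3 (0.95 ± 0.07) and Mt1 (1.07 ± 0.11), Txnrd1, thioredoxin reductase (0.47 ± 0.05), and Hmox1, the haem-degrading enzyme heme oxygenase 1 (2.20 ± 0.28). Of 26 hypoxia response genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.15): Bhlhe40 (1.36 ± 0.15), the vasodilator peptide Adm (0.88 ± 0.14) and Ndrg1 (0.87 ± 0.21) were higher and Mxi1, an antagonist of Myc, was lower (-0.83 ± 0.19). These 5 lists passed camera with the preset correlation (adjusted p from 1.17e-11 to 2.80e-04). With an estimated correlation the adjusted p was 0.0246, 0.0210, 0.0145, 0.0210 and 0.0211 in the order given. Of the members given here with a value, Tlr2, Bcl3, Ndrg1 and Mxi1 lost their calls with at least 1 array left out (highest adjusted p 0.17, for Ndrg1).

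The other 9 lists that passed at 0 h with the preset correlation of camera did not pass with an estimated one. By fry, 5 of these 9 also passed: immediate early genes (adjusted p = 0.0430), tubular injury markers (0.0455), cytokines (0.00451), STAT3 genes (0.0155) and p53 genes (0.00615). Of 26 cytokines and chemokines, 7 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.28). Beside Il1b, Ccl2 and Cxcl1, the macrophage growth factor Csf1 rose by 0.60 ± 0.11 on the log2 scale, and Il33 fell by 0.36 ± 0.08 (list adjusted p = 0.121 with an estimated correlation). Of 30 immediate early genes, the transcripts that respond first to a stimulus, 5 rose (8 adjusted over the list alone, median 0.43), among them Klf10 (1.02 ± 0.17), Mafk (1.04 ± 0.19), Atf3 (2.06 ± 0.39) and Klf6 (0.94 ± 0.20) (adjusted p = 0.243 with an estimated correlation). Of 19 STAT3 and acute phase genes, 2 rose, Cebpd and the receptor Il4r (1.05 ± 0.19), and 5 adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). Of 22 tubular injury markers, 3 rose, Tubb6 (1.22 ± 0.16), Clu (0.27 ± 0.07) and Anxa1 (0.57 ± 0.14), and 5 adjusted over the list alone (adjusted p = 0.273 with an estimated correlation). Of 25 p53 and apoptosis genes, 3 rose, Mcl1 (0.44 ± 0.07), Tnfrsf1a (0.84 ± 0.18) and Gadd45b (1.10 ± 0.25), and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.105 with an estimated correlation). In the neutrophil list S100a9 was the 1 of 11 members that passed, over all genes and adjusted over the list alone. Ncf4 (0.84 ± 0.28), Cxcr2 (0.13 ± 0.05) and Il1r2 (0.39 ± 0.15) did not (list adjusted p = 0.0127, and adjusted p = 0.439 with an estimated correlation). Antigen presentation, interferon and complement genes also passed at the preset correlation with 1, 0 and 0 members past the threshold, over all genes and adjusted over the list alone. With an estimated correlation their adjusted p was 0.495, 0.515 and 0.439. Of the members above that passed and are given with a value, only Tubb6 did so whichever array was left out. Those that did not were Csf1, Il33, Klf10, Mafk, Atf3, Klf6, Il4r, Clu, Anxa1, Mcl1, Tnfrsf1a and Gadd45b (highest adjusted p 0.165, for Il33). In all, 14 lists passed camera and 10 passed fry, and other splits of the same 6 arrays gave up to 15.

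Lists of kidney cell types did not pass at 0 h. Among 35 proximal tubule genes, Cyp24a1, the enzyme that breaks down active vitamin D (0.53 ± 0.11), and the bicarbonate transporter Slc4a4 (0.84 ± 0.20, and 0.56 without replicate 2 of the normal kidneys) rose, while the peptide transporter Slc15a2 (-0.87 ± 0.14) and the oxidase Hao2 (-0.45 ± 0.10) fell. The counts were 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.625). In the loop of Henle and distal nephron list, 1 of 21 genes fell, the calcium-sensing receptor Casr (-0.77 ± 0.15), also adjusted over the list alone (camera adjusted p = 0.0989). Of 16 endothelial cell genes 1 rose, Pecam1 (0.29 ± 0.06), and 3 adjusted over the list alone, although the list's median was -0.07 and its test pointed down (camera adjusted p = 0.625). Of 13 podocyte genes none passed (median 0.02, mean -0.03, camera adjusted p = 0.948). Among 21 T and NK cell genes the protease Gzma rose by 0.82 ± 0.15, over all genes and adjusted over the list alone. Medians of these leukocyte lists were 0.031 for monocytes and macrophages, 0.078 for T and NK cells and 0.088 for B cells (camera adjusted p = 0.189, 0.189 and 0.227). Each of the 7 genes that changed in these lists lost its call with at least 1 array left out (highest adjusted p 0.146, for Slc4a4).

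**Figure D1:**
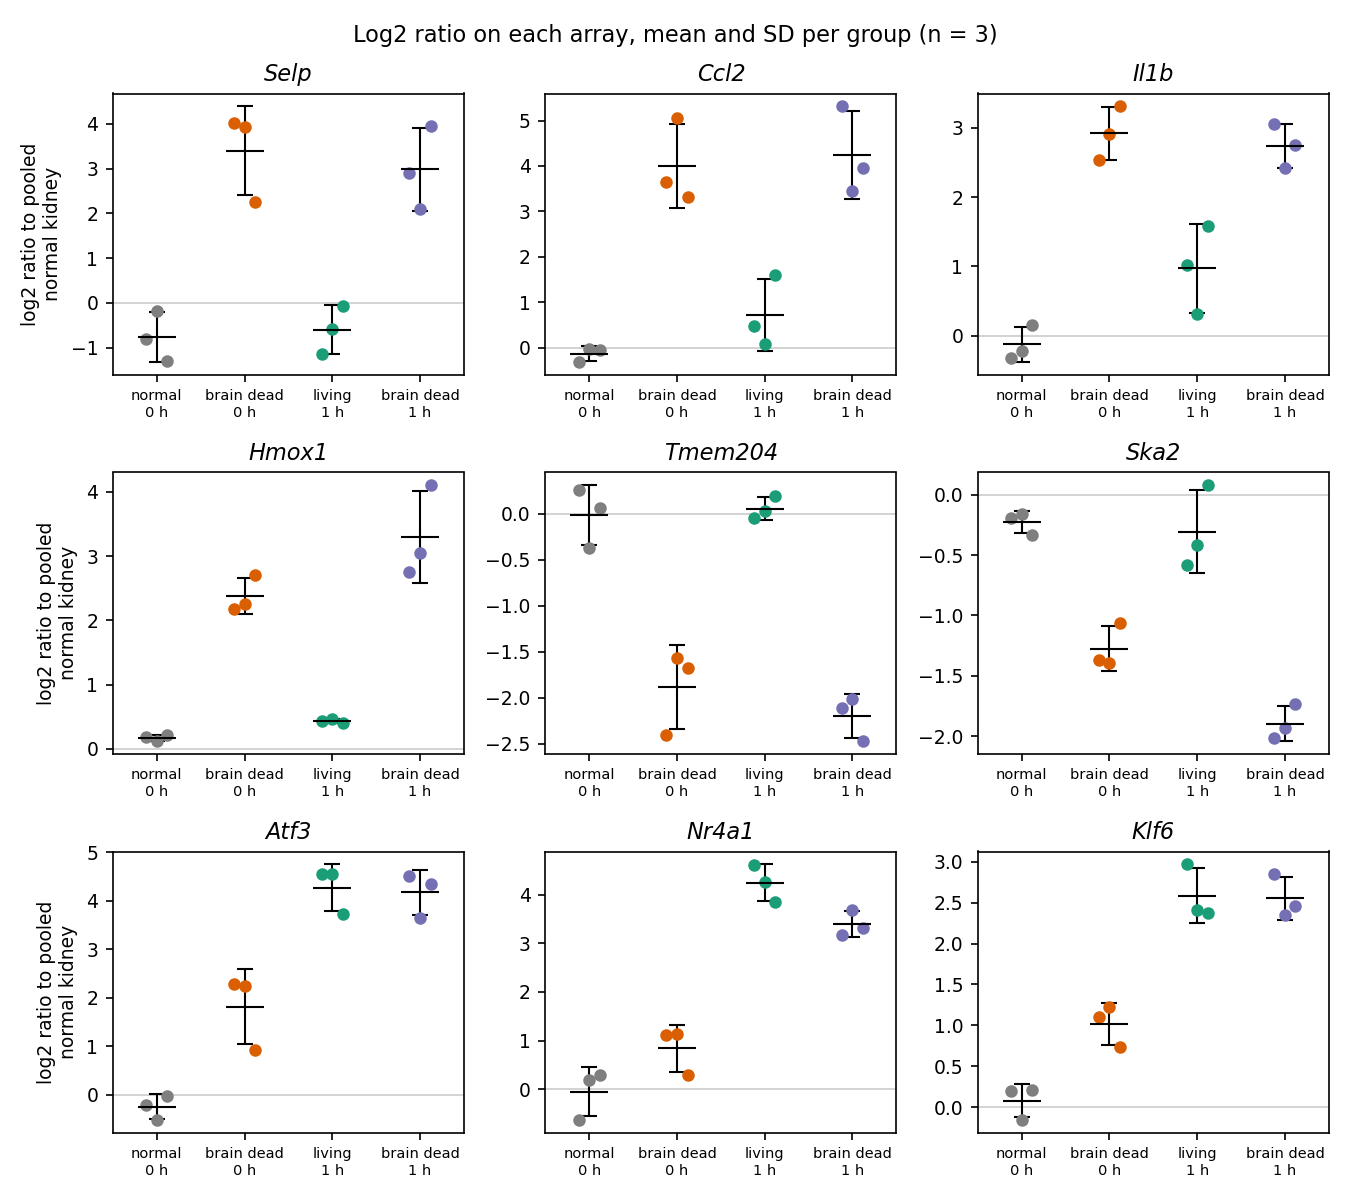
Log2 ratio to pooled normal kidney RNA (vertical axis, own scale in each panel) of 9 named genes on the 12 arrays, by group (horizontal axis); points are arrays, bars the mean and SD of 3 arrays. Selp, Ccl2, Il1b and Hmox1 lie higher and Tmem204 and Ska2 lower in both groups of brain dead donors, while Atf3, Nr4a1 and Klf6 lie highest in the 2 groups at 1 h.

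Grafts of brain dead and of living donors were compared to ask how they differed 1 h after transplantation. The adhesion molecule Selp was higher in grafts of brain dead donors by a log2 fold change of 3.59 ± 0.58 (SE, n = 3 arrays per group, adjusted p = 0.00840). Sele was 11.9-fold higher (log2 3.58 ± 0.67, adjusted p = 0.0138). Ccl2 was 11.5-fold (log2 3.53 ± 0.57) and Rnd1 9.73-fold higher (log2 3.28 ± 0.50). Hmox1 was 7.28-fold higher (log2 2.86 ± 0.28, adjusted p = 0.00161; its 2 probes gave 2.05 and 3.68). Cxcl1 was 5.39-fold and Il1b 3.41-fold higher (log2 2.43 ± 0.43 and 1.77 ± 0.32). Fabp1, a fatty acid binding protein, was 3.36-fold higher (log2 1.75 ± 0.39) and Igfbp1, a binding protein of insulin-like growth factors, 3.17-fold (log2 1.67 ± 0.25). Birc3 was 3.04-fold higher (log2 1.60 ± 0.40), the vasoactive peptide Apln 2.74-fold (log2 1.45 ± 0.27) and Plin2, a coat protein of lipid droplets, 2.36-fold (log2 1.24 ± 0.25). The 2 probes of Apln gave 1.13 and 1.78.

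Tmem204 again showed the largest decrease among the named genes that passed, to 0.210 of the level in living donor grafts (log2 -2.25 ± 0.23, adjusted p = 0.00163). Abi3, an adaptor of actin remodelling, stood at -2.19 ± 0.57 (adjusted p = 0.0482) but at -1.40 without replicate 21 of the brain dead donor grafts, Ska2 at -1.59 ± 0.16 (adjusted p = 0.00161), Nr0b2 at -1.48 ± 0.28 and Gja5 at -1.36 ± 0.20. Senp7, a SUMO protease, fell by 1.34 ± 0.15 on the log2 scale, Haus1, a subunit of the augmin complex of the spindle, by 1.31 ± 0.14, Ubac1 by 1.27 ± 0.16 and Atp10a by 1.22 ± 0.28. Filip1, Inpp5j and Stbd1, a glycogen-binding protein, fell by 1.21 ± 0.20, 1.18 ± 0.16 and 1.15 ± 0.22.

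In this comparison 1249 features passed in limma with Benjamini-Hochberg adjustment, 373 higher and 876 lower in grafts of brain dead donors, so that 70.1% were lower. Among named genes 241 were higher and 465 lower. Of the 1249, 100 changed at least 2-fold (39 higher, 61 lower). None of the 1249 showed overlap between replicates, against 25.8% of all features without overlap and 10% by chance. The count was 310 after quantile normalization, 427 in a fit of the 2 groups alone, 806 or 692 without replicate 21 or 27 of the brain dead donor grafts and 613, 723 or 557 without replicate 22, 24 or 25 of the living donor grafts. Of the 24 genes named above, 16 passed whichever array was left out, and Fabp1, Birc3, Apln, Plin2, Abi3, Nr0b2, Atp10a and Stbd1 did not (highest adjusted p 0.158, for Abi3).

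Genes of the antioxidant response were the 1 list that passed camera at both correlations at 1 h between donors. Of 28 oxidative stress and metallothionein genes, 9 were higher in grafts of brain dead donors (11 adjusted over the list alone, median 0.11), among them Mt3 (log2 0.87 ± 0.07), Hmox1, Mt1 (1.05 ± 0.11) and Txnrd1 (0.39 ± 0.05). This list passed camera with the preset correlation (adjusted p = 7.41e-05) and with an estimated one (adjusted p = 0.0216). NF-kB targets had 6 of 21 members higher (9 adjusted over the list alone, median 0.25). Among them were the mitochondrial superoxide dismutase Sod2 (1.09 ± 0.20), the receptor Cd40 (0.64 ± 0.13) and the kinase Ripk2 (0.64 ± 0.13). The list had an adjusted p = 0.00115 at the preset correlation and an adjusted p = 0.528 with an estimated correlation. Cytokines and chemokines had 5 of 26 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.20). Csf1 stood at 0.59 ± 0.11, beside Ccl2, Cxcl1 and Il1b (list adjusted p = 0.528 with an estimated correlation). Endothelial activation genes had 4 of 21 higher (7 adjusted over the list alone, median 0.11), Icam1 (1.13 ± 0.16), Selp, Sele and Plat (0.37 ± 0.09) (adjusted p = 0.110 with an estimated correlation). In the STAT3 list Il4r (1.03 ± 0.19) was the 1 member of 19 that rose, also adjusted over the list alone. In the heat shock list Hspa4 (-0.91 ± 0.09) was the 1 member of 22 that fell, also adjusted over the list alone (adjusted p = 0.682 and 0.725 for the STAT3 and heat shock lists with an estimated correlation). With 1 array left out, the calls of Cd40, Ripk2, Csf1 and Plat were each lost at least once (highest adjusted p 0.134, for Plat). These 6 lists passed in all, 5 of them upwards, and other splits of the same 6 arrays gave up to 11.

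Lists that did not pass camera between the grafts also held single genes that passed in limma. Of 21 vasoactive genes 2 were lower, the natriuretic peptide receptor Npr1 (-0.42 ± 0.05) and the endothelin Edn3 (-0.34 ± 0.07), with 2 lower and 1 higher adjusted over the list alone. This list had a camera adjusted p = 0.818 but passed fry (adjusted p = 0.0384). Of 25 p53 genes 3 were higher, Tnfrsf1a, Mcl1 and Tp53inp1 (camera adjusted p = 0.270, fry adjusted p = 0.0384). Each of these 3 lost its call with at least 1 array left out (highest adjusted p 0.103, for Tp53inp1). Among 23 unfolded protein genes Slc7a5 (0.75 ± 0.13) and Sesn2 (0.63 ± 0.12) were higher and Ddit3, the stress transcription factor CHOP, was lower (-0.57 ± 0.10), with 2 and 1 adjusted over the list alone (camera adjusted p = 0.278). Slc15a2 (-0.94 ± 0.14) and Hao2 (-0.41 ± 0.10) were lower and Cyp24a1 (0.59 ± 0.11) was higher among 35 proximal tubule genes, with the same counts adjusted over the list alone (camera adjusted p = 0.822). The podocyte sialomucin Podxl (-0.61 ± 0.14) and the fibroblast receptor Pdgfra (-0.55 ± 0.12) were the members of their lists that fell, with 3 and 1 lower adjusted over the list alone (camera adjusted p = 0.822 and 0.286). The podocyte list had a median of 0.05 but a mean of -0.08 and a test that pointed down. S100a9 stood at 1.78 ± 0.50 (adjusted p = 0.0652), and no member of the neutrophil list passed, over all genes or adjusted over the list alone (camera adjusted p = 0.332). Edn3, Sesn2, Hao2, Podxl and Pdgfra lost their calls with at least 1 array left out (highest adjusted p 0.114, for Podxl).

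The donor comparisons at 0 h and at 1 h share no array, so they were set side by side to ask whether the genes that differed before transplantation were those that differed after it. In both, 491 features passed in the same direction, 181 higher and 310 lower, and none passed in opposite directions. Independent lists of these lengths would share 8.5 and 20.9. The 2 lists are not independent, because the same fit gives both comparisons 1 estimate of each feature's spread. A feature with a low estimate can thus pass in both, and 8.5 and 20.9 are not an exact baseline. Fits of 2 groups alone do not share this estimate and gave 81 shared features, for which no count of independent lists was computed. Among named genes 121 were higher and 172 lower at both times, against 6.6 and 11.6 for independent lists. They included Selp, Ccl2, Rnd1, Sele, Cxcl1, Hmox1, Il1b and Igfbp1 on the higher side and Tmem204, Nr0b2, Ska2 and Gja5 on the lower. Igfbp1 stood at 2.23 ± 0.25 at 0 h and 1.67 ± 0.25 at 1 h, and Fabp1 at 2.01 ± 0.39 and 1.75 ± 0.39, though Fabp1 lost its call at both times with 1 array left out (highest adjusted p 0.0757 at 0 h). Fold changes correlated across the 9653 named genes with Pearson's r of 0.677 and Spearman's rho of 0.556, where genes are not independent replicates. Of 505 named genes that passed at 0 h, 490 (97.0%) had the same sign at 1 h. The shared count was 205 after quantile normalization, 980 with array weights, 81 in fits of 2 groups alone, and between 114 (without replicate 2 of the brain dead donor kidneys) and 732 (without replicate 1 of them) when 1 array was left out. Without replicate 3 of those kidneys it was 193, without replicate 1, 2 or 3 of the normal kidneys 174, 159 or 202, and without replicate 22, 24 or 25 of the living donor grafts 266, 283 or 300.

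**Figure D2:**
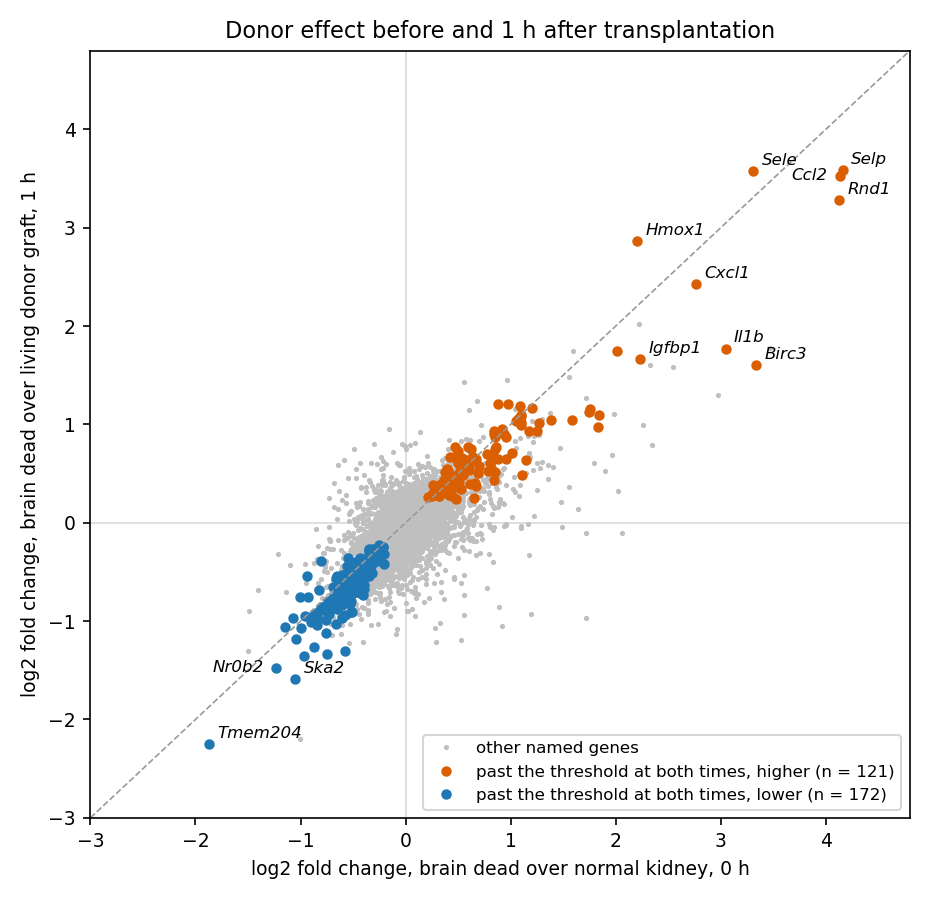
Log2 fold change of brain dead over normal kidney at 0 h (horizontal axis) against brain dead over living donor graft at 1 h (vertical axis) for 9653 named genes; coloured points passed in the same direction at both times (121 higher, 172 lower) and the dashed line marks equal values. Selp, Ccl2, Rnd1 and Sele lie at the upper end and Tmem204 at the lower end.

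Grafts of living donors 1 h after transplantation were compared with normal kidneys to describe what transplantation itself did. Fos, a subunit of the AP-1 transcription factor, was 38.1-fold higher (log2 5.25 ± 0.82, SE, n = 3 arrays per group, adjusted p = 0.0230). The stress transcription factor Atf3 was higher by a log2 fold change of 4.52 ± 0.39 (adjusted p = 6.40e-04). The nuclear receptor Nr4a1 was 19.6-fold (log2 4.29 ± 0.31, adjusted p = 5.88e-04) and the zinc finger factor Egr1 14.2-fold higher (log2 3.83 ± 0.57). Nr4a3 rose 9.59-fold (log2 3.26 ± 0.62) and Hspa1a, an inducible heat shock chaperone, 9.49-fold (log2 3.25 ± 0.26). Also higher were Ccn1, a matrix-associated signalling protein, 7.60-fold (log2 2.93 ± 0.31) and Rasd1 7.40-fold (log2 2.89 ± 0.42). Klf6, Nfkbia, Ppp1r15a and Klf4 rose 5.67-fold, 5.36-fold, 4.66-fold and 4.66-fold. The 5 named genes that fell were Cenpf, a kinetochore protein (-0.77 ± 0.13), Simc1 (-0.73 ± 0.13), Igsf10 (-0.54 ± 0.09), Fmo4 (-0.51 ± 0.09) and Igf2bp2 (-0.38 ± 0.07), and the 2 probes gave -1.36 and -0.19 for Cenpf and -0.74 and -0.03 for Igf2bp2. Over all arrays, 7 values of the Cenpf probes and 1 of the Igf2bp2 probes were exact zeros.

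In limma with Benjamini-Hochberg adjustment 135 features passed, 100 higher and 35 lower, and 75 were named genes (70 higher, 5 lower). Of the 135, 70 changed at least 2-fold, and all showed no overlap between replicates (18.5% of all features, 10% by chance). The lower share, 25.9%, was 36.4% after quantile normalization (195 features) and 40% with array weights (483 features). It was 16.3% or 13.9% without replicate 1 or 3 of the normal kidneys and 15.2% or 17.5% without replicate 22 or 24 of the living donor grafts. The count was 43, 55 or 36 without replicate 1, 2 or 3 of the normal kidneys, and 33, 57 or 210 without replicate 22, 24 or 25 of the living donor grafts. Of the 17 genes named above, 8 passed whichever array was left out, and Fos, Egr1, Nr4a3, Rasd1 and all 5 that fell did not (highest adjusted p 0.205, for Nr4a3).

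Of the 30 immediate early genes, 19 rose after transplantation from living donors (26 adjusted over the list alone, median 1.43), with Nr4a1, Klf6, Atf3 and Klf4 as the members with the smallest p. Among 23 unfolded protein and ATF4 response genes 5 rose (8 adjusted over the list alone, median 0.26), among them Atf4 (1.24 ± 0.10), Ppp1r15a, Ddit3 (1.23 ± 0.10) and Herpud1 (0.79 ± 0.08). Of 26 hypoxia response genes 2 rose, Ddit4, an inhibitor of mTOR signalling (1.19 ± 0.11), and Adm (0.84 ± 0.14, adjusted p up to 0.145 with 1 array left out), and 4 adjusted over the list alone (median 0.13). These 3 lists passed camera with the preset correlation (adjusted p = 6.22e-39, 4.42e-12 and 4.95e-05) and with an estimated correlation (adjusted p = 0.00812, 0.00661 and 0.0133).

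With the preset but not with an estimated correlation, 11 more lists passed camera, and 4 of them also passed fry: endothelial activation (adjusted p = 0.00374), glucocorticoid responsive (0.00863), p53 (0.00863) and smooth muscle genes (0.0420). Endothelial activation genes had 2 of 21 higher (2 adjusted over the list alone), Edn1, the vasoconstrictor endothelin 1 (1.29 ± 0.17), and F3, tissue factor (0.86 ± 0.12), and the adjusted p was 0.0612 with an estimated correlation. Glucocorticoid responsive genes had 3 of 23 higher (7 adjusted over the list alone), Ddit4, Tsc22d3 (0.90 ± 0.16) and the clock gene Per1 (1.76 ± 0.31) (adjusted p = 0.0798 with an estimated correlation). NF-kB targets had 2 of 21 higher (4 adjusted over the list alone), Nfkbia and Cd83 (0.83 ± 0.15) (adjusted p = 0.206 with an estimated correlation). Heat shock genes had 2 of 22 higher, Hspa1a and its partner Dnajb1 (0.51 ± 0.09), and 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.486 with an estimated correlation). Tubular injury markers and p53 genes each had 1 member higher, Anxa1 (1.02 ± 0.14) and Gadd45b (1.90 ± 0.25), with 5 higher for the first and 4 higher and 1 lower for the second adjusted over the list alone (adjusted p = 0.206 and 0.0740 with an estimated correlation). Cytokines, antigen presentation and interferon genes had no member past the threshold, over all genes or adjusted over the list alone, and each had an adjusted p of 0.486 with an estimated correlation. Smooth muscle, pericyte and fibroblast genes had none over all genes and 2 higher adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). The proximal tubule list was the 1 list that moved down (median -0.12), with no member past the threshold over all genes and 1 lower adjusted over the list alone. The amino acid transporter Slc6a18 stood at -0.24 ± 0.05 and the phosphate transporter Slc34a1 at -0.38 ± 0.12 (list adjusted p = 0.00211, and adjusted p = 0.247 with an estimated correlation). Edn1, F3, Tsc22d3, Per1, Cd83, Dnajb1, Anxa1 and Gadd45b lost their calls with at least 1 array left out (highest adjusted p 0.159, for Dnajb1 and Per1). The 14 lists compare with up to 12 in other splits of the same 6 arrays.

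Grafts of brain dead donors at 1 h were compared in the same way with brain dead donor kidneys at 0 h. Nr4a1 rose 5.86-fold (log2 2.55 ± 0.31, SE, n = 3 arrays per group, adjusted p = 0.0315), and Klf6 rose 2.89-fold (log2 1.53 ± 0.20, adjusted p = 0.0339). Ddit4 rose 2.03-fold (log2 1.02 ± 0.11), F3 1.93-fold (log2 0.95 ± 0.12) and Tgif1, a repressor of TGF-beta signals, 1.56-fold (log2 0.65 ± 0.08). These were the named genes among the 10 features that passed in limma with Benjamini-Hochberg adjustment (7 higher, 3 lower). The balance turned with 1 array left out, to 77.8% lower of 9 features without replicate 27 of the grafts and 58.3% lower of 12 without replicate 23. None of the 5 passed whichever array was left out, and their highest adjusted p was then 0.176, for F3. All 10 showed no overlap between replicates (18.8% of all features, 10% by chance). No feature passed without replicate 21 of the grafts, without replicate 2 or 3 of the brain dead donor kidneys or without replicate 3 of the normal kidneys, nor after quantile normalization or in a fit of the 2 groups alone. Without replicate 1 of the normal kidneys 2 features passed and without replicate 24 of the living donor grafts 3, and with array weights 68, of which 44.1% were lower against 30% before.

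Among the 30 immediate early genes 2 rose in brain dead donor grafts, Nr4a1 and Klf6, and 20 adjusted over the list alone, with a median of 0.82. Atf3 stood at 2.36 ± 0.39 and Ccn1 at 1.93 ± 0.31, both short of the threshold over all genes. The list passed with the preset correlation of camera (adjusted p = 2.98e-20) and had an adjusted p = 0.12 with an estimated correlation. By fry it was the 1 list that passed in this comparison (adjusted p = 0.00775). Unfolded protein genes passed upwards with no member over all genes and 3 adjusted over the list alone, with Atf4 at 0.55 ± 0.10 and Ddit3 at 0.55 ± 0.10 (adjusted p = 0.0405, and adjusted p = 0.309 with an estimated correlation). Proximal tubule genes passed downwards with no member over all genes or adjusted over the list alone and a median of -0.18. The anion transporter Slc22a6 stood at -0.47 ± 0.14 and the endocytic receptor Lrp2 at -0.39 ± 0.12, while Slc22a7 stood at 0.27 ± 0.07 (list adjusted p = 0.00258, and adjusted p = 0.382 with an estimated correlation). Other splits of the same 6 arrays gave up to 10 lists against these 3.

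The changes of grafts from living and from brain dead donors, which also share no array, correlated across named genes with Pearson's r of 0.523 and Spearman's rho of 0.376. All 75 named genes that passed in living donor grafts had the same sign in brain dead donor grafts, and 5 of them passed there. Whether the change differed between donors was asked with the interaction of donor and time, and no feature passed in limma (964 at an unadjusted p under 0.05, 924 by chance, smallest adjusted p 0.0648). With array weights 3 features passed, among them H3f3b (adjusted p = 0.0397), and with named genes alone 1 did, H3f3b (adjusted p = 0.0209). Without replicate 22, 24 or 25 of the living donor grafts 1, 1 or 4 features passed, and H3f3b was among them without replicate 24 or 25 (its adjusted p with 1 array left out lay between 0.0207 and 0.353). The smallest p-values belonged to H3f3b, a histone H3.3 gene (log2 -1.53 ± 0.17, adjusted p = 0.0648), Nfkbia (-1.82 ± 0.29), Ppp1r15a, Hspa1a (-2.12 ± 0.37) and Herpud1 (-0.62 ± 0.11), the last 4 with an adjusted p of 0.473. In H3f3b the mean log2 ratio was -0.06 in normal kidney, 1.44 in brain dead donor kidneys, 1.68 in living donor grafts and 1.64 in brain dead donor grafts. Ppp1r15a stood at 0.39, 1.57, 2.61 and 2.29 in the same order, Hspa1a at 0.09, 1.29, 3.34 and 2.41, and Nfkbia at 0.31, 2.03, 2.74 and 2.63.

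As lists, 10 passed for the interaction at the preset correlation of camera, all downwards, and other splits of the arrays gave up to 16. A negative interaction means that the difference of brain dead from other donors lay lower at 1 h than at 0 h, which can be a smaller difference or one of the opposite sign. Unfolded protein and ATF4 response genes, whose median donor difference was 0.30 at 0 h and 0.08 at 1 h, had a median interaction of -0.26, with no member past the threshold over all genes and 4 lower adjusted over the list alone. Those 4 were Ppp1r15a, Herpud1, Atf4 (-0.69 ± 0.14) and Ddit3 (-0.69 ± 0.14). This list passed with the preset correlation (adjusted p = 8.75e-07) and with an estimated one (adjusted p = 0.0451). Immediate early genes, whose median donor difference was 0.43 at 0 h and -0.23 at 1 h, had a median interaction of -0.57, with no member over all genes and 5 lower adjusted over the list alone. Nr4a1 stood at -1.74 ± 0.44, Atf3 at -2.16 ± 0.55, Klf10 at -0.95 ± 0.24 and Klf4 at -1.23 ± 0.33 (list adjusted p = 4.12e-09, and adjusted p = 0.238 with an estimated correlation).

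**Figure D3:**
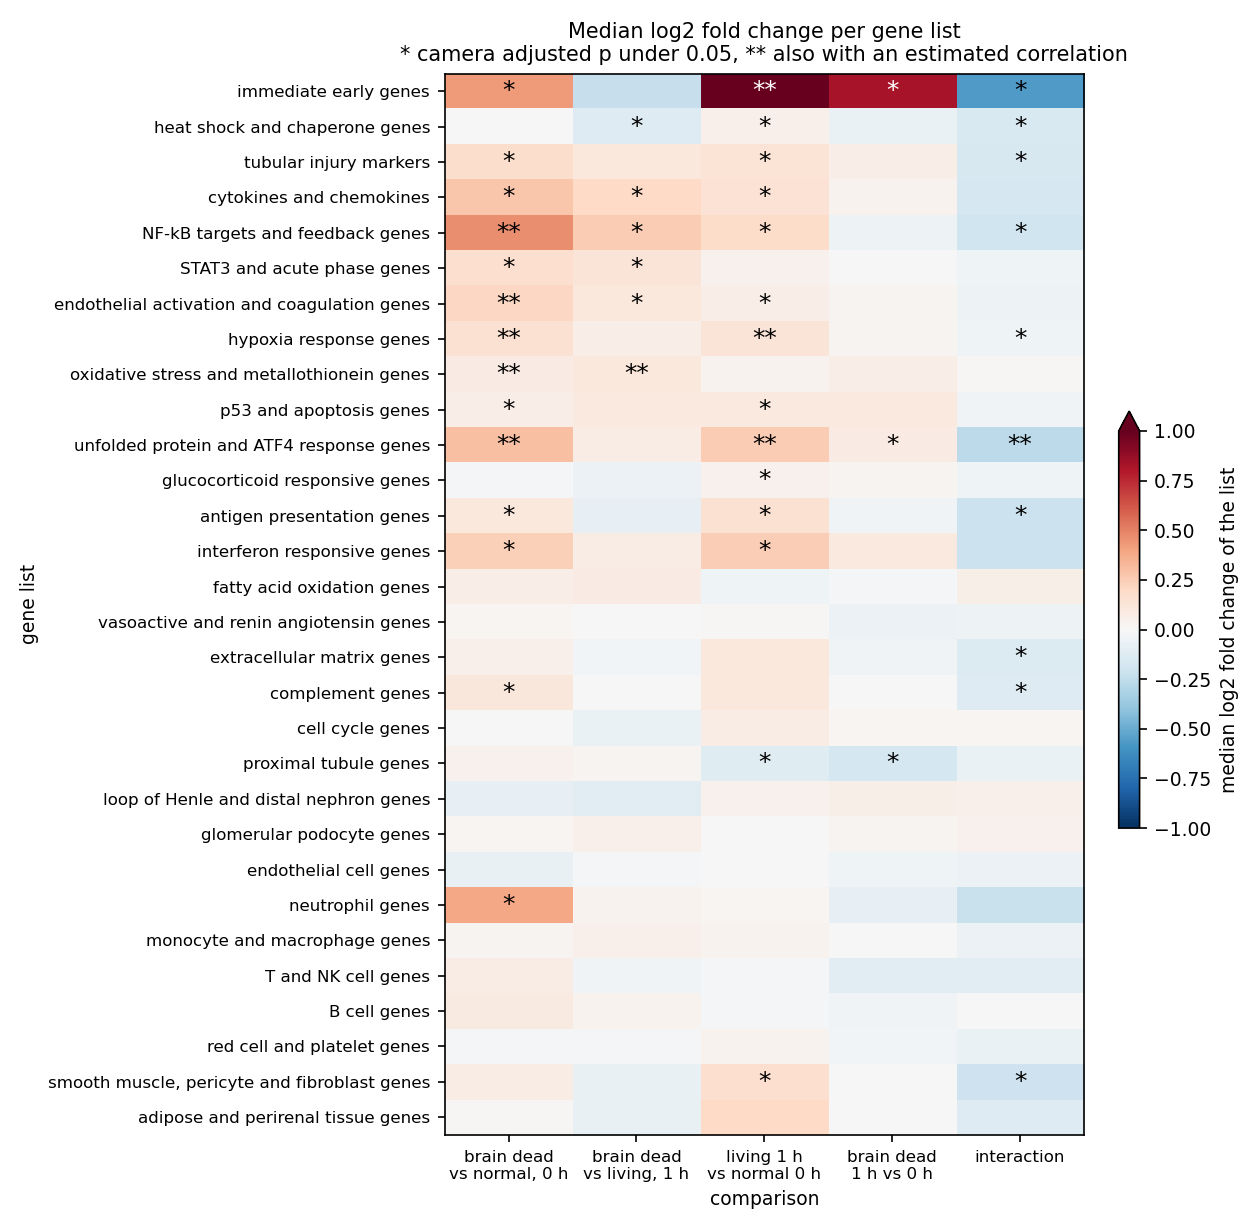
Median log2 fold change (colour, deepest from 1 upwards) of the measured members of 30 gene lists (vertical axis) in the 5 comparisons (horizontal axis), where an asterisk marks a camera adjusted p under 0.05 and a second asterisk one that held with an estimated correlation. Immediate early genes have the highest median, 1.43, in grafts of living donors, and the interaction column holds the lowest, -0.57, for the same list.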

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

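The test of whether immediate early genes were already raised before transplantation was chosen after the result was seen.

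In 10 gene lists the difference of brain dead from other donors lay lower at 1 h than at 0 h, by camera's test of the interaction of donor and time at the preset correlation. The median difference was positive at both times in NF-kB targets (0.462 and 0.251), unfolded protein genes (0.297 and 0.077), tubular injury markers (0.177 and 0.102), hypoxia response genes (0.152 and 0.063) and complement genes (0.112 and 0.004, where the mean at 1 h was -0.041). Its sign turned in immediate early genes (0.429 and -0.233), antigen presentation genes (0.102 and -0.084), smooth muscle genes (0.074 and -0.078) and extracellular matrix genes (0.053 and -0.026). In heat shock genes it was -0.003 at 0 h and -0.131 at 1 h, where the list passed downwards (adjusted p = 0.725 with an estimated correlation). Unfolded protein and ATF4 response genes had a median interaction of -0.264 on the log2 scale, and theirs was the 1 list that also passed with an estimated correlation (adjusted p = 0.0451). Immediate early genes had a median of -0.567 (adjusted p = 0.238 with an estimated correlation), and heat shock and chaperone genes one of -0.15, where Hspa1a was the 1 member lower adjusted over the list alone (adjusted p = 0.428 with an estimated correlation). NF-kB targets and feedback genes had a median of -0.203, with Nfkbia as the 1 lower member adjusted over the list alone, and hypoxia response genes one of -0.045, with Bhlhe40 (adjusted p = 0.428 and 0.234 with an estimated correlation). Smooth muscle, pericyte and fibroblast genes had a median of -0.208, with Pdgfra (adjusted p = 0.238 with an estimated correlation). No member passed adjusted over the list alone among tubular injury markers (median -0.157), antigen presentation genes (-0.211), extracellular matrix genes (-0.133) and complement genes (-0.126). With an estimated correlation their adjusted p was 0.538, 0.552, 0.437 and 0.538. Without replicate 1 of the brain dead donor kidneys, or without replicate 23 of the brain dead donor grafts, 5 lists passed.

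Splits of the arrays bear on these list counts. For the interaction, 14 of 100 drawn splits gave 10 or more lists (highest 16 in the others), so chance cannot be excluded for the number of lists. For single genes all 100 splits gave at least the real count of 0, and 1 split called 2685 genes, which points to a structure of the samples: when donor labels are mirrored at 1 of the times, the interaction becomes the sum of the donor effects.

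For the group comparisons there are only 10 splits of 6 arrays, too few for a share under 0.1. The number of splits with a count of genes as large as the real one was 1 for brain dead against normal kidneys (860, highest other 0), 1 for brain dead against living donor grafts (1249, highest other 1), 1 for living donor grafts against normal kidneys (135, highest other 0) and 1 for brain dead donor grafts against brain dead donor kidneys (10, highest other 0). For lists the number was 2 (14, highest other 15), 3 (6, highest other 11), 1 (14, highest other 12) and 6 (3, highest other 10) in the same order. For the 491 genes shared by both donor comparisons, 1 of 100 drawn splits, the real one, gave a count as large (highest other 0). In each of the others a donor comparison called at most 1 gene, or 1 time had its donor labels mirrored, so no count near 491 was possible and this says nothing about the overlap.

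The 1st pattern weighed is that 70.1% of the features that differed between grafts at 1 h were lower in grafts of brain dead donors. After quantile normalization, where 310 features passed, it was 72.3%, against a normalization between arrays as the cause. Centring each array kept 1242 of the 1249 features and moved too little to test this. Without replicate 21, 23 or 27 of the brain dead donor grafts it was 70.3%, 77.2% or 72.7%, against a single array as the cause. The lowess step applied before deposition could not be undone and stays open. So does the donor's brain death with its ventilation, which the design names and which was not tested apart from that step.

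The 2nd pattern is that 10 features passed for transplantation in brain dead donors and 135 in living donors, but at an unadjusted p under 0.05 the order turns, with 2423 and 2013 (924 by chance), and the difference itself passed for no feature in limma (964 at that p, and 3 passed with array weights), so a smaller response is not shown. Leaving out 1 of the 6 arrays of brain dead donors gave at most 14 features. So low a count had been set as the result that would speak against a single array as the cause. But it leaves 2 arrays in a group, which lowers the power, so a low count could arise either way. Array weights, which leave no array out, gave 68 features against 483 in living donors. These counts cannot decide on a single array as the cause. The median SD between replicates in brain dead donor groups was 1.08 times that in the other groups. The fit gives both comparisons the same estimate of each feature's spread, so this ratio cannot decide whether a larger spread is the cause. A candidate explanation is that immediate early genes were already raised before transplantation: their median interaction was -0.567, but the list's adjusted p with an estimated correlation was 0.243 at 0 h and 0.238 for the interaction. Both tests also use the same brain dead donor arrays at 0 h, so a high value there raises the first and lowers the second, and this explanation cannot be told apart from that.

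The 3rd pattern is S100a9, which was 11.1-fold higher in brain dead donor kidneys before transplantation. For blood retained in the kidney, the median log2 fold change of 9 measured red cell and platelet genes was -0.016 (SD 0.172, highest 0.469, for Gp5). A median below 1 by more than its spread had been set as the result that would speak against blood, but no haemoglobin gene was measured and without intensities the other genes may lie near background, so blood cannot be told apart. For neutrophils, the 10 other genes of the list had a median of 0.26, 7 of them higher, and camera p was 0.0338 at the preset correlation and 0.262 with an estimated one. The preset test had been chosen to decide, but it also passed many lists in other splits of the same arrays, so more neutrophils in the kidney stay open as a candidate explanation, as does S100a9 made by kidney cells, which was not tested.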

How the results depend on the processing

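Tests of exact zeros taken as missing and of named genes alone were chosen after the data were seen. No single gene followed and no list that passed changed sign under any alternative tried. Where probes were single features, each gene followed was judged by its probe with the smallest p, so another probe that disagreed could not count. Of 164 single genes followed that had passed, 32 passed under every alternative run for them, and of 47 lists that passed, 10 did. The number of genes that passed stayed within 1.5 times its value in all 5 contrasts with centred arrays, 0.1 added to the ratio, limited ratios, robust eBayes, zeros taken as missing, probes with a value other than 0 on all arrays, and probes as single features. Where counts moved further, the cause was not tested unless given. Quantile normalization gave 310 genes for brain dead against living donor grafts, 0 for brain dead donor grafts against kidneys at 0 h and 205 in both donor comparisons. Array weights gave 2852 for brain dead against normal kidneys (858 of the 860 among them), 483 for living donor grafts against normal kidneys (all 135 among them), 68 for brain dead donor grafts against kidneys at 0 h (all 10 among them), 3 for the interaction and 980 in both. With named genes alone, where fewer features are tested, the counts were 813 for brain dead against living donor grafts, 86 for living donor grafts against normal kidneys, 6 for brain dead donor grafts against kidneys at 0 h and 1 for the interaction (H3f3b). Fits of only the 2 groups compared, which estimate the spread from fewer arrays, gave 350 for brain dead against normal kidneys, 427 for brain dead against living donor grafts, 0 for brain dead donor grafts against kidneys at 0 h and 81 in both. A threshold of 2-fold left 123, 100, 70 and 4 genes in the 4 group comparisons. Adding the replicate number as a block to the fit of the 2 groups at 0 h alone, which gave 350, left 2 genes. Whether the numbers pair the arrays is not settled. Deviations from the group mean of arrays with the same number correlated with r of 0.328, 0.1 and 0.034. Replicates 2 and 3 of the brain dead donor kidneys each correlated better with another number. Deviations within so small a group depend on each other, so these values cannot decide for or against pairing. Lists that passed with an estimated correlation numbered 5, 1, 3, 0 and 1 in the 5 contrasts, and with fry 7 passed for living donor grafts against normal kidneys, 1 for brain dead donor grafts against kidneys at 0 h and 2 for the interaction.

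Leaving out 1 array at a time, where 2 arrays then stand for a group, gave 165 to 1186 genes for brain dead against normal kidneys (lowest without replicate 2 of the brain dead donor kidneys; 304, 239 and 362 without normal replicates 1, 2 and 3, 333 without replicate 3 of the brain dead donor kidneys). For brain dead against living donor grafts the range was 557 to 1526 (806 and 692 without brain dead donor grafts 21 and 27; 613, 723 and 557 without living donor grafts 22, 24 and 25). For living donor grafts against normal kidneys it was 33 to 210 (43, 55 and 36 without normal replicates 1, 2 and 3; 33, 57 and 210 without living donor grafts 22, 24 and 25). For brain dead donor grafts against kidneys at 0 h it was 0 to 14, for the interaction 0 to 4, and in both donor comparisons 114 to 732. Lists for the interaction ranged from 5 to 11. Signal over background was not used here, so what it limits could not be measured.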

Other observations

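Gene groups not yet described held single genes that passed. Fkbp5, a chaperone of the glucocorticoid receptor, rose by 1.18 ± 0.25 on the log2 scale in brain dead donor kidneys at 0 h, as the 1 of 23 glucocorticoid responsive genes that passed, also adjusted over the list alone (SE, n = 3 arrays per group, limma with Benjamini-Hochberg adjustment). The list's median was -0.02, against a mean of 0.09 and a test that pointed up (camera adjusted p = 0.775). Acox2, a peroxisomal oxidase, fell by 0.76 ± 0.17 at 0 h, the 1 of 25 fatty acid oxidation genes that passed, also adjusted over the list alone (median 0.07, camera adjusted p = 0.0963). At 1 h Acot1 (0.43 ± 0.09) and Cpt1a, which brings fatty acids into mitochondria (0.61 ± 0.15), were higher in grafts of brain dead than of living donors, 2 of 25 over all genes and adjusted over the list alone (camera adjusted p = 0.0667). The protease Mmp14 rose by 0.48 ± 0.09 at 0 h, the 1 of 20 extracellular matrix genes that passed, also adjusted over the list alone (camera adjusted p = 0.0543). Among 21 vasoactive genes at 0 h, Edn1 rose (0.74 ± 0.17) and Npr1 fell (-0.20 ± 0.05), with 2 and 2 adjusted over the list alone (camera adjusted p = 0.607). Each of these 7 genes lost its call with at least 1 array left out (highest adjusted p 0.171, for Npr1).

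Heat shock genes at 0 h moved both ways: Hspa1a (1.19 ± 0.26) and Dnaja4 (0.28 ± 0.06) rose and Hspa4 (-0.52 ± 0.09) fell, with 3 higher and 1 lower of 22 adjusted over the list alone. The list's median was -0.00, against a mean of 0.06 and a test that pointed up (camera adjusted p = 0.625). Each of these 3 lost its call with at least 1 array left out (highest adjusted p 0.122, for Dnaja4). In living donor grafts Pcna, a clamp of DNA replication, rose by 0.51 ± 0.06 and Cenpf fell, 1 and 1 of 24 cell cycle genes over all genes and adjusted over the list alone (camera adjusted p = 0.185). At 0 h no cell cycle gene passed (median 0.00, mean -0.07, test down, camera adjusted p = 0.625). No gene passed at 0 h, over all genes or adjusted over the list alone, among 9 red cell and platelet genes, where the median was -0.02 and the mean 0.05 (camera adjusted p = 0.943). The same held for 13 smooth muscle, pericyte and fibroblast genes (median 0.07, camera adjusted p = 0.181), 9 adipose genes (median 0.01, camera adjusted p = 0.775) and 5 B cell genes.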
